A study of Mus musculus with 2 samples.

How the data were processed

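Total RNA of 2 samples of G1ME cells, a mouse line, was DNase-treated, biotin-labelled and hybridised to Affymetrix arrays, per the labels' protocols. The deposited log2 values are those of GCRMA, per the submitters' processing notes, a method that corrects each probe for background by its base content and sums probes into 1 value per probe set. The GCRMA version, its settings and the arrays normalized together are not given in the sources used here. The log2 scale was inferred from the values, which ran from 0.39 to 14.2. GCRMA pulls dim probe sets towards a common low level, so differences among dim genes are compressed. The series' value table and its complete matrix, which per the series text also covers re-analysed arrays of another series, held identical values for all 45101 probe sets of these 2 samples. The complete matrix also holds 8 columns of samples outside this series, which were not used. No scanner files were used, so background and normalization were taken as the authors left them.

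Genes were named from the platform annotation, which lists 35890 of the probe sets. Of these, 34958 list 1 gene and 932 list several, and no gene was named from the latter. For 34754 probe sets the Entrez ID matched the RefSeq gene table of GRCm38.p6 and 204 kept the annotation's symbol, and no symbol changed. The other 9211 probe sets have no gene listed in the annotation used and were left out of gene counts. Of all probe sets, 64 have identifiers of array controls. No genome was used, and coordinates are not given because the files name no build.

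All choices below except those named as added were made before the data were examined. The floor of an array was the 95th percentile of its 44 probe sets for olfactory receptor genes (39 genes). A gene was above the floor if at least 1 of its probe sets exceeded it on both arrays. A gene's printed level is that of its probe set with the highest mean over both arrays. The 24 gene lists (458 entries, 416 with a probe set naming that gene alone, 413 distinct genes) were compared with all other named genes by two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. The other 42 entries were not analysed here. Genes are not independent replicates, so these p-values describe the lists on these arrays and not other cultures. Exact binomial intervals (Clopper-Pearson, 95%) cover the number of genes only. The floor and the choice of a gene's probe set did set levels of different probe sets against each other. So did the matching of random lists on level. Differences in response between probe sets were not corrected for in these steps beyond GCRMA. Genes were not ranked by level.

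The text names Gata1, then for each list, in the order it was written, the first 4 members above the floor and the first 2 not above it, then the 5 genes with the largest difference between arrays in each direction among probe sets above the floor on both. Of the 134 genes so named, 57 have 1 probe set and 35 have probe sets on both sides of the floor. Srgn, Hoxd8, Acta2, Esam, Irf9, 9 genes of the erythroid list and Hba-a2, which is in no list, were named beyond this rule, after their values were seen. The 35 are Runx1, Hdc, Csf1r, Cd4, Cd8a, Zap70, Eed, Ezh1, Rnf2, Cbx2, Kdm6a, Kdm6b, Hoxa5, Hoxb4, Pax6, Hand1, Utf1, Col1a1, Col5a1, Pdgfra, Pdgfrb, Nes, Ncam1, Eng, Top2a, Tbp, Fdps, Pdk1, Aplp2, Gbf1, Laptm5, Igbp1, Gpr146, Mapk6 and Ube2k.

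Array agreement was taken over probe sets whose mean exceeded the mean floor of 2.70. For list shifts a gene was read by its probe set with the highest mean, and the list's median difference was placed among 10000 random lists matched on deciles of level. With 1 array against 1, no p-value was computed for these. As an alternative call, limma's one-group fit of value minus floor with eBayes was used, one-sided, with 1 residual and 3.98 prior degrees of freedom. No paired analysis applies, as there is 1 group.

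The calls above the floor were tested on simulated arrays built on the levels of these 2 arrays. Their noise was drawn from the arrays' difference divided by 2, so the simulated arrays differed less than the real ones. Recovery at the real spread, a per-array SD of 0.27, was not tested. The list steps used the real values. All 100 probe sets placed 1 above the floor and all 100 placed 3 above it were called by the direct rule (45101 probe sets run). The limma test also called them all (34958 run). Of 200 left more than 0.5 below the mean floor, 0 were called by either. No negatives nearer the floor were simulated, so this gives no rate of false calls there. Of 100 random lists of 20 genes, 6 had an unadjusted Fisher's exact p below 0.05. Of 2000 random lists of 15 genes, 6.15% fell outside the central 95%, and 93 of 100 lists shifted by 0.3 were found (10396 genes run).

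Alternatives were the 90th and 99th percentiles and fixed values of 4 and 6 as floor, probe sets without the suffixes of shared sets, every probe set above the floor, either array, the limma call, quantile normalization, centring, the complete matrix and each replicate alone. A fixed floor of 5 and a Monte Carlo test matched on the number of probe sets were added after the data were seen. In each of its 100000 draws, every list member was set above the floor or not at random. The probability was the share above the floor among genes with as many probe sets. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1 were used.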

Results

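G1ME cells are a mouse line that the series text describes as megakaryocyte-erythroid cells lacking Gata1, the gene of a transcription factor needed for red cell and platelet precursors to mature. The cells were grown with thrombopoietin, the cytokine that drives platelet production, and received no treatment. Total RNA was hybridised to Affymetrix mouse arrays, on which each gene is read by 1 or more probe sets. The 2 samples, replicates 1 and 2, form 1 group with no control group, so the values describe what these cells transcribed and how closely the arrays agreed. The series pairs this profile with maps of the repressive histone mark H3K27me3, which were not analysed here. The labels do not say whether the replicates came from separate cultures, so SDs and limma's p-values measure only the spread between these samples, which may be technical. The p-values of gene lists take genes as units and measure no spread between arrays. Each value below is a log2 GCRMA value, given as the mean ± SD of the 2 arrays (n = 2). The number of arrays limits its precision.

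Each array held 45101 probe sets. The floor was the 95th percentile of 44 probe sets for olfactory receptor genes. These were assumed to have little or no RNA in the cells, which was not tested. It was 2.65 on replicate 1 and 2.75 on replicate 2. Replicate 1 had 21415 probe sets above its floor (47.5%) and replicate 2 had 20646 (45.8%). Of the 18194 genes named by the annotation, 9964 (54.8%) had at least 1 probe set above the floor on both arrays. A further 628 genes were above it on replicate 1 only and 352 on replicate 2 only. In the limma one-group test of level against the floor, 9439 genes lay above it at an adjusted p below 0.05. Of the 413 distinct genes in the 24 lists, 222 were above the floor by the direct rule. The limma test called 220 over all genes tested and 220 adjusted over the list alone.

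Gata1 itself was above the floor on both arrays, at 9.41 ± 0.08, with 9.35 on replicate 1 and 9.47 on replicate 2. The array held 1 Gata1 probe set. The series text calls the cells Gata1 null while the sample labels give the genotype as wild type, and neither says which part of the gene was altered. Without the position of the probe set relative to that part, its value does not check either label.

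The first question was which blood-lineage programmes gave signal. Transcription factors of early blood cells were present as a group, with 18 of 21 measured genes above the floor. Gata2 reached 10.80 ± 0.11 and its partner Tal1 10.67 ± 0.11. The bridging factor Lmo2 stood at 10.32 ± 0.02 and Runx1, a regulator of blood stem cell formation, at 8.88 ± 0.42. Erg (2.40 ± 0.28) and Mecom (2.01 ± 0.21) were not above the floor. The list had more genes above the floor than other named genes did (85.7% against 54.7%, two-sided Fisher's exact test, adjusted p = 0.00918).

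Megakaryocyte and platelet genes were mostly above the floor, 17 of 23, among them genes of the platelet surface receptors. Itga2b, the alpha subunit of the fibrinogen receptor, reached 10.77 ± 0.49, and its partner Itgb3 9.13 ± 0.14. Pf4, a chemokine of platelet granules, stood at 11.41 ± 0.03, and Gp9, part of the von Willebrand factor receptor, at 8.55 ± 0.06. Gp6, the collagen receptor (2.68 ± 0.02), and Vwf (2.41 ± 0.20) were not above the floor. The share, 73.9% against 54.7% of other genes, did not pass the test (adjusted p = 0.110, Fisher's exact test). It passed in 5 of 14 alternatives (adjusted p from 0.0123 to 0.171 over all 14, Fisher's exact or Monte Carlo test). Among the 5 was replicate 1 alone, with 82.6% of members above the floor (adjusted p = 0.0329, Fisher's exact test).

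Erythroid genes were split, with 9 of 23 above the floor and 14 not. The erythropoietin receptor gene Epor was at 3.79 ± 0.19, the erythroid factor Klf1 at 5.11 ± 0.39, and the membrane protein gene Epb42 at 5.82 ± 0.54. Tfrc, the transferrin receptor, which other growing cells also use, reached 11.32 ± 0.01. Alas2, the erythroid enzyme that starts haem synthesis, stayed at 1.86 ± 0.06, and the red cell anion exchanger Slc4a1 at 2.61 ± 0.04. Others above the floor, named after their values were seen, were the haem pathway enzymes Fech (10.30 ± 0.19), Urod (9.83 ± 0.01) and Cpox (8.10 ± 0.05), the mitochondrial iron carrier Slc25a37 (7.74 ± 0.01) and carbonic anhydrase Car2 (12.24 ± 0.26). Read by probe sets that list 1 gene, the alpha-globin gene Hba-a1 and the embryonic globins Hba-x, Hbb-bh1 and Hbb-y were not above the floor. These were also named after their values were seen. Of 4 probe sets that list several globin genes, 2 were above it, at 2.94 ± 0.04 and 4.51 ± 0.19, and both list Hba-a1 and Hba-a2. Alpha-globin Hba-a2, which is in no list, was also above the floor by a probe set of its own, at 3.15 ± 0.33. The list did not pass the test (39.1% against 54.8% of other genes, Fisher's exact test, adjusted p = 0.159).

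In 4 lists of other blood lineages, most measured genes were not above the floor. In the mast cell and basophil list 5 of 15 were above it, including the stem cell factor receptor Kit (7.35 ± 0.84), the protease Cpa3 (9.59 ± 0.07), Mitf (5.63 ± 0.09), Hdc (3.08 ± 0.43) and the proteoglycan Srgn (11.55 ± 0.17). Fcer1a (1.78 ± 0.03) and Ms4a2 (2.01 ± 0.35), which form the high-affinity IgE receptor, were not, and the share did not pass the test (adjusted p = 0.138, Fisher's exact test). In the granulocyte and monocyte list 6 of 21 were above the floor, fewer than among other genes (28.6% against 54.8%, Fisher's exact test, adjusted p = 0.0376). The granule genes Mpo (3.18 ± 0.08) and Prtn3 (4.88 ± 0.26), the factor Spi1 (5.31 ± 0.02) and the receptor Csf1r (3.36 ± 0.09) were among the 6, while Elane (1.93 ± 0.13) and Ctsg (2.28 ± 0.15) were not. This call ended in 5 of 14 alternatives (adjusted p from 0.0161 to 0.436 over all 14, Fisher's exact or Monte Carlo test). Among these 5 was the Monte Carlo test against genes with as many probe sets, added after the data were seen (adjusted p = 0.312). For B lymphoid genes the count was 1 of 14 (adjusted p = 0.00194), the receptor gene Cd79b at 3.39 ± 0.35, with Pax5 at 2.25 ± 0.21 and Cd79a at 1.99 ± 0.08 below the floor. For T and NK genes it was 3 of 14 (adjusted p = 0.0277, both by Fisher's exact test), namely Zap70 (5.26 ± 0.31), Cd8a (3.69 ± 0.12) and Cd4 (3.24 ± 0.27). The T cell receptor components Cd3e (2.19 ± 0.15) and Cd3d (1.93 ± 0.18) were not above it.

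**Figure D1:**
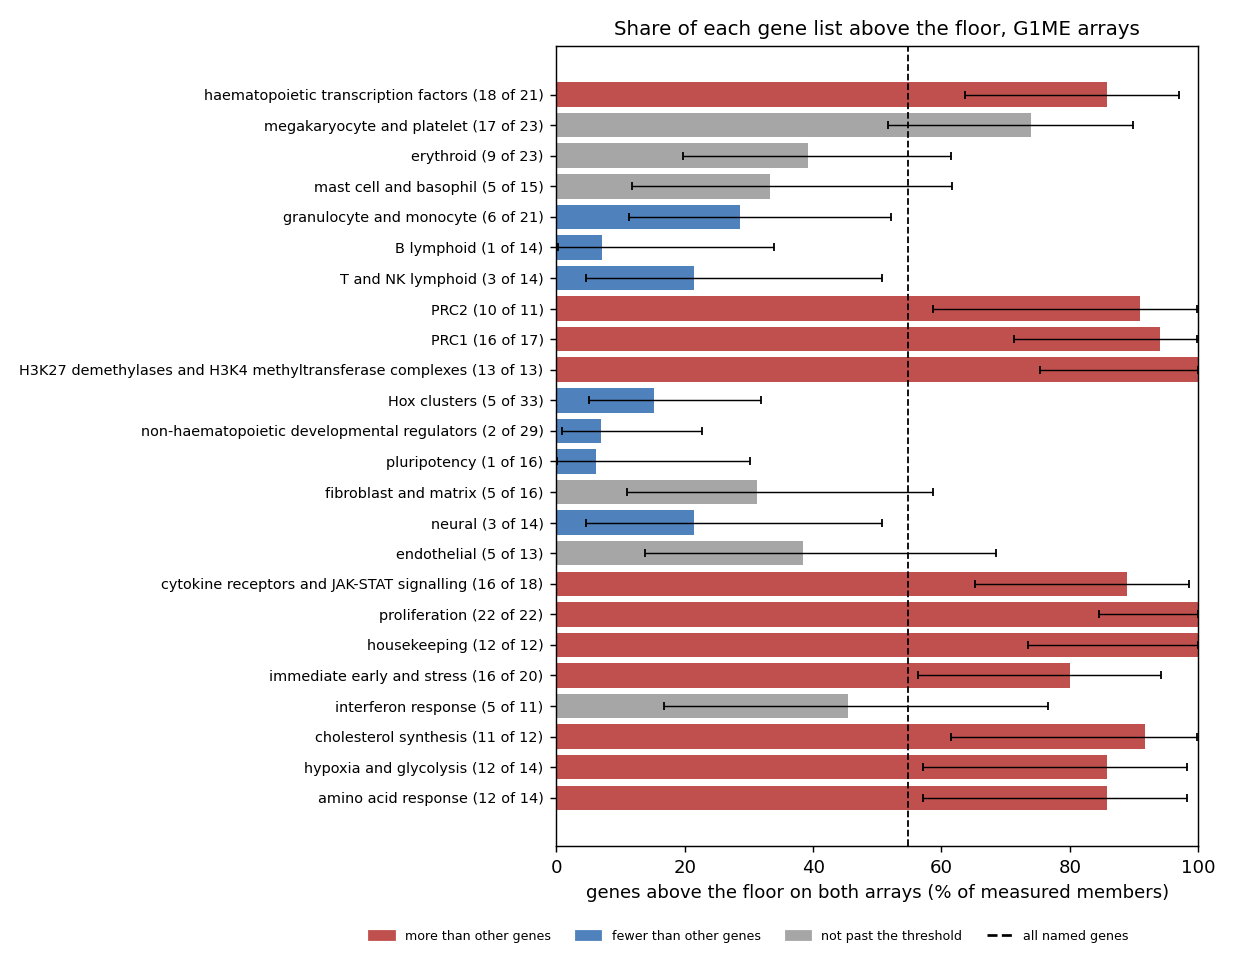
Bars give the percent of each list's measured genes that lay above the floor on both G1ME arrays, with exact 95% binomial intervals as error bars, and the dashed line marks the 54.8% of all named genes. Red bars lie above and blue bars below the share among other genes by Fisher's exact test, with 18 of 21 haematopoietic transcription factors and 1 of 14 B lymphoid genes above the floor.

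The second question was whether the machinery that writes, reads and removes H3K27me3 was transcribed. Polycomb repressive complex genes were nearly all above the floor. In PRC2, which deposits the mark, 10 of 11 genes were above it, with the catalytic subunit Ezh2 at 9.90 ± 0.16 and the core subunits Suz12 at 10.49 ± 0.05 and Eed at 9.95 ± 0.13. The other catalytic subunit, Ezh1, was at 5.63 ± 0.30, and Phf19 (2.76 ± 0.08) had no probe set above the floor on both arrays, though a different one of its 2 probe sets was above it on each. The share exceeded that of other genes (90.9% against 54.7%, Fisher's exact test, adjusted p = 0.0277), but the call ended in 2 of 14 alternatives (adjusted p from 0.00897 to 0.278 over all 14). The call ended in a test against genes with as many probe sets (adjusted p = 0.210, Monte Carlo test). It also ended under the rule that every probe set lie above the floor (54.5%, adjusted p = 0.278, Fisher's exact test). In PRC1, which binds the mark and modifies histone H2A, 16 of 17 were above the floor (adjusted p = 0.00253, Fisher's exact test), with Bmi1 at 9.62 ± 0.03, Rnf2 at 8.74 ± 0.11, Ring1 at 6.90 ± 0.10 and Cbx2 at 5.74 ± 0.23. Cbx7 (2.61 ± 0.13) was the exception. All 13 genes of the H3K27 demethylases and H3K4 methyltransferase complexes were above the floor (adjusted p = 0.00194, Fisher's exact test). Only Kdm6a and Kdm6b of this list remove H3K27me3, so its test mostly covers the H3K4 complexes. The demethylases Kdm6a and Kdm6b stood at 7.97 ± 0.13 and 9.71 ± 0.39, and the methyltransferases Kmt2a and Kmt2b at 6.75 ± 0.19 and 9.01 ± 0.15.

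Developmental regulators, a class that carries H3K27me3 in many cell types, were largely not above the floor. Of 33 measured Hox genes, which set position along the body axis, 5 were above it (15.2% against 54.8%, Fisher's exact test, adjusted p = 3.12e-05). These were Hoxa5 (6.18 ± 1.07), Hoxa7 (3.23 ± 0.01), Hoxb4 (3.26 ± 0.28), Hoxb13 (3.44 ± 0.29) and Hoxd8 (3.25 ± 0.16). Hoxa2 (1.65 ± 0.14) and Hoxa3 (2.63 ± 0.21) were not, and none of the 7 measured Hoxc genes were. With the floor at a fixed 4 the count was 1, namely Hoxa5, and it was 10 on replicate 1 alone, 6 on replicate 2 alone, 11 on either array and 14 with the 90th percentile as floor. Hoxa5 was above the floor by 1 of its 2 probe sets, and that one carries the suffix of shared sets. Without shared probe sets Hoxa5 lost its place and the Hox count was 4. The share stayed below that of other genes in all 14 alternatives (adjusted p from 1.30e-06 to 0.0487, Fisher's exact or Monte Carlo test). Among 29 other developmental regulators of non-blood tissues, 2 were above the floor (6.90%, adjusted p = 2.13e-06, Fisher's exact test). Pax6, an eye and brain factor, reached 7.17 ± 0.21, with 3 of its 5 probe sets above the floor, and Hand1 was at 3.20 ± 0.15. The endoderm and heart factors Gata4 (2.33 ± 0.39) and Sox17 (2.14 ± 0.33) were not above it.

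Markers of other lineages were above the floor in a minority of cases. Of 16 pluripotency genes, 1 was above the floor (adjusted p = 0.000373, Fisher's exact test), Utf1 at 3.07 ± 0.15, with Pou5f1 (1.79 ± 0.20) and Nanog (2.01 ± 0.32) not above it. On replicate 1 alone the count was 2. Of 14 neural genes, 3 were (adjusted p = 0.0277, Fisher's exact test), namely Ncam1 (5.35 ± 0.27, by 1 of 7 probe sets), Tubb3 (4.17 ± 0.10) and Nes (3.13 ± 0.17), while Gfap (2.04 ± 0.05) and Fabp7 (1.70 ± 0.02) were not. Of 16 fibroblast and matrix genes, 5 were above it (adjusted p = 0.0978, Fisher's exact test). Col1a1 (3.16 ± 0.19), Col5a1 (3.33 ± 0.44), Pdgfra (2.79 ± 0.16), Pdgfrb (3.05 ± 0.18) and Acta2 (3.71 ± 0.64) lay close to the floor, and Col1a2 (1.91 ± 0.05) and Col3a1 (2.21 ± 0.19) were not above it. With the floor at a fixed 4 the count was 0 of 16 (adjusted p = 0.000437, Fisher's exact test), and over all 14 alternatives the adjusted p ran from 0.000437 to 0.152, with 6 past the threshold. Of 13 endothelial genes, 5 were above it (adjusted p = 0.285, Fisher's exact test). Pecam1 (7.61 ± 0.69), Tie1 (7.88 ± 0.03) and Esam (7.17 ± 0.13) are also transcribed in some blood cells. Kdr was at 3.42 ± 0.19 and Eng at 4.85 ± 0.34, and Cdh5 (1.89 ± 0.23) and Tek (2.01 ± 0.16) were not above the floor.

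**Figure D2:**
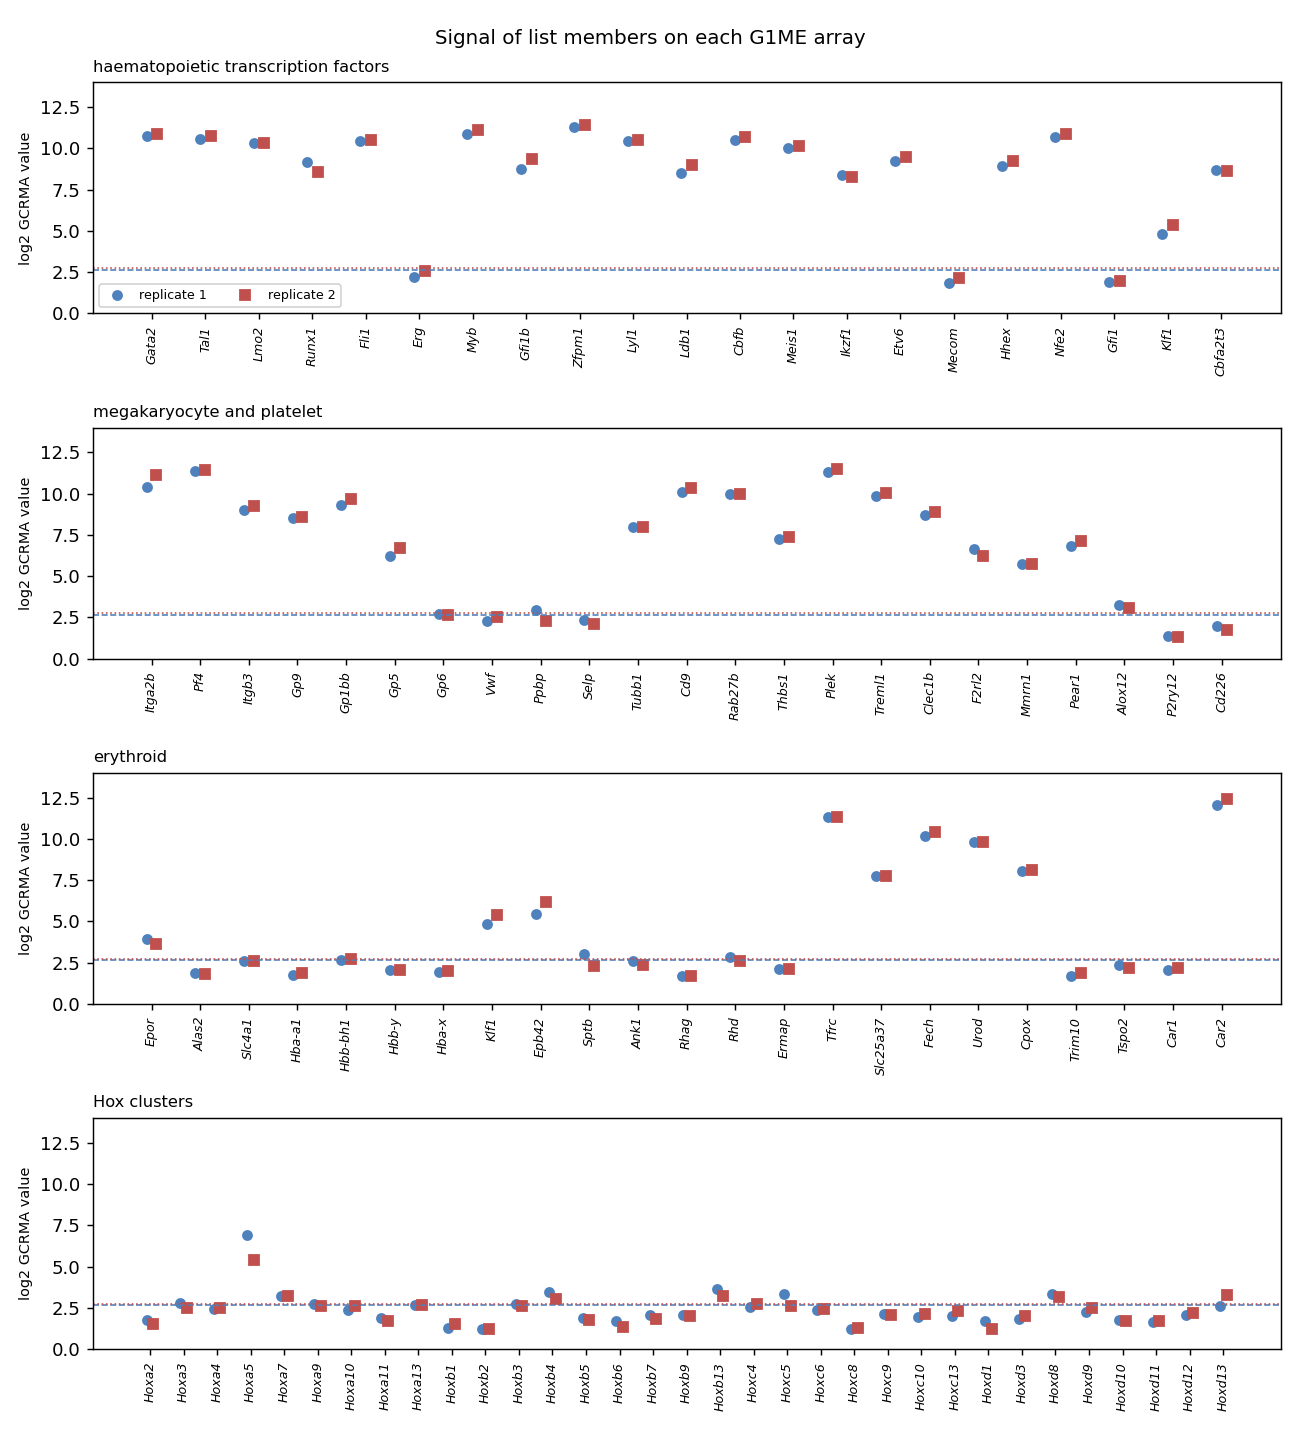
Points give the log2 GCRMA value of each measured member of 4 lists on replicate 1 (circles) and replicate 2 (squares), and the dashed and dotted lines mark the floors of replicate 1 (2.65) and replicate 2 (2.75). Most transcription factors and megakaryocyte genes sit far above both lines, Alas2 and Slc4a1 below them, and most Hox genes near or below them. Hoxa5 lies at 6.18 on average by 1 of its 2 probe sets, and the other was not above the floor.

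The third question was whether genes of growth, signalling, metabolism and stress gave signal. All 22 measured proliferation genes were above the floor (adjusted p = 2.96e-05, Fisher's exact test), with Mki67 at 11.11 ± 0.13, Ccna2 at 10.12 ± 0.15, Cdk1 at 10.76 ± 0.14 and Top2a at 11.35 ± 0.10. In the cytokine receptor and JAK-STAT list 16 of 18 were (adjusted p = 0.00910, Fisher's exact test). They included Csf2rb, the shared receptor chain of several myeloid cytokines (11.47 ± 0.10), and Il3ra (3.79 ± 0.15), besides Kit and Epor. Csf2ra (2.74 ± 0.06) and Flt3 (2.32 on replicate 1 and 2.68 on replicate 2) were not above the floor on both arrays. With a fixed floor of 6 this list held 10 of 18 and the call ended (adjusted p = 0.167, Fisher's exact test). It ended in 2 of 14 alternatives in all, over which the adjusted p ran from 0.00384 to 0.167. All 12 housekeeping genes were above the floor (adjusted p = 0.00253, Fisher's exact test), with Actb at 13.60 ± 0.07, Gapdh at 13.28 ± 0.23, Hprt at 10.88 ± 0.24 and Tbp at 7.62 ± 0.01.

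Of 12 cholesterol synthesis genes, 11 were above the floor (adjusted p = 0.0277, Fisher's exact test), among them Hmgcs1 (11.84 ± 0.06), Sqle (10.31 ± 0.08), Idi1 (12.53 ± 0.14) and Fdps (11.40 ± 0.12), but not Insig1 (1.66 ± 0.09). The hypoxia and glycolysis list held 12 of 14 (adjusted p = 0.0376, Fisher's exact test), with the glucose transporter gene Slc2a1 at 11.38 ± 0.05, Bnip3 at 11.16 ± 0.22, Pdk1 at 9.95 ± 0.08 and Vegfa at 7.79 ± 0.10. Adm (2.48 ± 0.15) and Car9 (2.25 ± 0.01) were not above the floor. The amino acid response list also held 12 of 14 (adjusted p = 0.0376, Fisher's exact test). Asns, asparagine synthetase, was at 11.11 ± 0.14, the serine pathway genes Phgdh and Psat1 at 11.42 ± 0.20 and 11.29 ± 0.14, and Chac1 at 5.76 ± 0.63, while Slc7a11 (2.57 ± 0.22) and Vldlr (2.46 ± 0.18) were not above it. Neither of the last 2 calls held on replicate 1 alone (adjusted p = 0.0685 for each, Fisher's exact test). Both also ended against genes with as many probe sets (adjusted p = 0.141 and 0.161, Monte Carlo test). Over 14 alternatives the adjusted p ran from 0.000678 to 0.141 for hypoxia and glycolysis, from 0.00236 to 0.161 for the amino acid response and from 0.000423 to 0.0548 for cholesterol synthesis, whose call ended in 2.

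Of 20 immediate early and stress genes, 16 were above the floor (adjusted p = 0.0376, Fisher's exact test). Egr1 reached 10.81 ± 0.24, Ier2 10.53 ± 0.21, Junb 8.58 ± 0.10 and Jun 6.46 ± 0.09, while Fos (2.12 ± 0.11) and Fosb (1.45 ± 0.01) were not above it. On either replicate alone this call did not pass (adjusted p = 0.0557 without replicate 1 and 0.0808 without replicate 2, Fisher's exact test). Over 14 alternatives its adjusted p ran from 0.0153 to 0.128. Interferon response genes were divided, 5 of 11 (adjusted p = 0.560, Fisher's exact test). Bst2 (8.42 ± 0.09), Oas1a (8.52 ± 0.21), Ifit2 (5.88 ± 0.12), Usp18 (4.18 ± 0.30) and Irf9 (5.66 ± 0.14) were above the floor, and Ifit1 (1.66 ± 0.00) and Ifit3 (2.26 ± 0.17) were not.

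The arrays agreed closely. Over the 20881 probe sets with a mean above the mean floor, Pearson's r across probe sets was 0.990 and Spearman's rho 0.984, with probe sets not being independent replicates. The difference, replicate 2 minus replicate 1, had an SD of 0.38 and a median of 0.11, and 83.9% of probe sets differed by less than 0.5. In all, 503 probe sets (2.41%) differed by at least 1 on the log2 scale, 284 higher on replicate 2 (56.5%) and 219 higher on replicate 1. After quantile normalization the split was 212 to 277 (43.4%), so its direction depended on the scaling. Centring, which moves every probe set by the same amount, gave 180 to 314 (36.4%). With 1 array against 1 these differences have no replicate check. The 5 genes with the largest differences towards replicate 1 were Aplp2 (-3.76), Gbf1 (-3.15), Laptm5 (-3.06), Samhd1 (-2.94) and Igbp1 (-2.83). Towards replicate 2 they were Ncf1 (3.53 on replicate 1 and 6.02 on replicate 2), Cd200r1 (2.33), Gpr146 (2.31), Mapk6 (2.25) and Ube2k (2.18). The other probe sets above the floor for the first 5 genes had median differences of -0.17, 0.32, 0.17, -0.14 and 0.25. For Samhd1 this median covers a further probe set that fell with the first, from 7.28 on replicate 1 to 4.86 on replicate 2. For the latter 5 genes these were 1.14, 0.60, -0.08, 0.10 and 0.08.

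**Figure D3:**
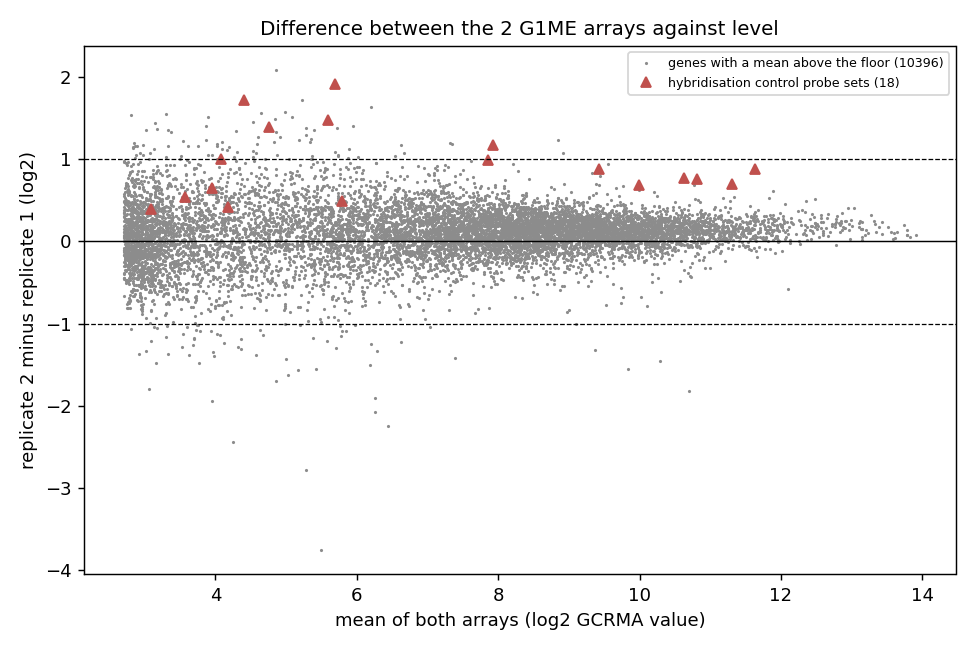
Each grey point is 1 of 10396 genes with a mean above the floor, plotted by its mean log2 GCRMA value and by replicate 2 minus replicate 1, and triangles are the 18 hybridisation control probe sets. Dashed lines mark differences of 1 in either direction, genes scatter more at low levels, and all 18 controls lie above 0.

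Among lists with at least 5 genes above the floor, 2 of 19 shifted between the arrays beyond the central 95% of 10000 random lists matched on level. Of simulated lists with no shift, 6.15% fell outside that range, which is about 1 of 19. The 12 hypoxia and glycolysis genes were higher on replicate 2 by a median of 0.27, 12 of 12 in that direction, at percentile 99.8. Random lists matched to them on level had a median of 0.14. The count of 12 was not particular to this list, since 12 of 12 housekeeping genes were also higher on replicate 2, at percentile 45.8. The direction held under every scaling tried, with a median of 0.11 after quantile normalization and 0.15 after centring. The 8 Hox genes with a mean above the floor had a median of -0.31, at percentile 1.70, and 3 of 8 were higher on replicate 2. Without shared probe sets the Hox percentile was 7.88. The 11 PRC2 genes lay inside the range, with a median of 0.02 at percentile 3.41, and outside it after quantile normalization, with a median of -0.13 at percentile 1.60.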

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

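The test of the hybridisation controls was chosen after their values were seen.

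Outside the named genes, 1582 of 9160 probe sets with no gene listed in the annotation used, array controls left out, lay above the floor on both arrays (17.3%), against 17536 of 34958 probe sets with 1 gene listed (50.2%). They drew attention because the report's comparisons do not use them.

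Hybridisation control probe sets, which read bacterial and phage transcripts added to the labelled sample, were brighter on replicate 2 by a median of 0.82, with 18 of 18 higher and a range of 0.39 to 1.91. They drew attention as a signal outside the gene measurements. More control per amount of labelled sample on replicate 2 may account for it, since poly-A controls, added before labelling, shifted by 0.21 (95% interval 0.05 to 0.37), against a median of 0.11 for all probe sets above the mean floor. Over all 24 poly-A probe sets the range was -0.18 to 1.51, which overlaps that of the hybridisation controls. The interval takes probe sets as units, though several read the same added transcript, and measures no spread between arrays. A difference in overall brightness stays open, since the values were processed before deposit, and no biological explanation was tested.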

How the results depend on the processing

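The fixed floor of 5 and the comparison matched on the number of probe sets were chosen after the data were seen, and the other alternatives were planned. The complete matrix holds identical values, and quantile normalization keeps the order of probe sets within an array, on which the floor also rests. Neither could therefore test a list's share above the floor, and neither changed a call. Both are still counted among the 14 alternatives. Quantile normalization did move the PRC2 shift outside the range of random lists (median -0.13, percentile 1.60). Transcription factors, both lymphoid lists, PRC1, H3K27 and H3K4 enzymes, Hox, developmental, pluripotency, neural, proliferation and housekeeping lists kept their direction and their side of the threshold in all 14 alternatives. Erythroid, mast cell and endothelial lists passed in none of the 14. The cause of the changes below was not tested, except that a higher floor removes dim genes by construction.

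With the 99th percentile as floor, granulocyte and monocyte genes lost their call (28.6%, adjusted p = 0.0587, Fisher's exact test). With the 90th, immediate early (80%, adjusted p = 0.126), cholesterol (91.7%, adjusted p = 0.0548) and hypoxia genes (85.7%, adjusted p = 0.121) did, by Fisher's exact test. With that floor 14 Hox, 6 developmental, 3 pluripotency and 3 B lymphoid genes were above it against 5, 2, 1 and 1. Fixed floors of 4, 5 and 6 put megakaryocyte genes past the threshold (69.6%, 69.6% and 65.2%) and fibroblast genes too, with 0% above each. The cytokine list lost its call at 5 (61.1%) and 6 (55.6%). Without shared probe sets, granulocyte genes lost the call (30%) and fibroblast genes gained one (25%). With every probe set required, 6569 genes were above the floor against 9964, granulocyte (23.8%) and PRC2 genes (54.5%) lost their calls, fibroblast genes (0%) gained one, and interferon genes (45.5%) turned direction without passing. Under limma, megakaryocyte genes passed (73.9%) and granulocyte genes did not (28.6%). On either array, immediate early (80%), cholesterol (91.7%), hypoxia and amino acid genes (85.7% each) lost their calls. Matched on probe sets, granulocyte (28.6%), PRC2 (90.9%), hypoxia and amino acid genes (85.7% each) lost their calls, fibroblast genes (31.3%) gained one, and interferon genes (45.5%) turned against an expected 43.0%.

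On each replicate alone, megakaryocyte genes ran from 73.9% to 82.6%, and immediate early (80%), hypoxia (85.7%) and amino acid genes (85.7%) kept their percent while other genes' share rose. The number of probe sets higher by at least 1 on replicate 1 was 123 at a floor of 4, and at 6 there were 62 higher on replicate 2 and 41 on replicate 1. Centring left 180 higher on replicate 2. The Hox shift had no value at floors of 4 and 6, where fewer than 5 members were left. Signal over background limits the dim genes. Of 134 named genes, 20 lost their place above the floor at 4, 24 at 5 and 36 at 6, and 35 when every probe set was required, and 7 gained it with the 90th percentile.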

Other observations

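The gene lists of the next 2 paragraphs, and all tests in this part, were chosen after the report's values were seen.

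Enzymes that act on DNA methylation and histone acetylation were mostly above the floor. Of 6 DNA methylation genes, 5 were, with the maintenance methyltransferase Dnmt1 at 10.71 ± 0.21, the de novo enzymes Dnmt3a at 7.64 ± 0.32 and Dnmt3b at 9.53 ± 0.05, and the oxidase Tet2 at 7.25 ± 0.66, while Tet3 (2.45 ± 0.32) was not (adjusted p = 0.405, Fisher's exact test, n = 2). Of 11 histone deacetylase genes, 10 were, among them Hdac1 (10.09 ± 0.16) and Hdac2 (10.24 ± 0.06) but not Hdac9 (2.47 ± 0.19), and the share did not pass after adjustment over 7 lists (adjusted p = 0.110, Fisher's exact test). The MYC family and cell-cycle inhibitor list held 7 of 9 (adjusted p = 0.405, Fisher's exact test), with Mycn at 11.96 ± 0.01, Myc at 9.44 ± 0.22 and the inhibitor Cdkn1a at 11.31 ± 0.17, and Mycl (1.95 ± 0.07) not above the floor.

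Surface and antigen-presentation genes were divided. Of 20 integrin genes, 11 were above the floor (adjusted p = 1, Fisher's exact test), including Itga6 (10.57 ± 0.02), Itgal (9.44 ± 0.05), Itgb2 (9.52 ± 0.05) and Itgb1 (9.47 ± 0.26). Of 11 stem and progenitor surface antigens, 5 were (adjusted p = 0.754, Fisher's exact test), with Slamf1 at 8.72 ± 0.10, Cd44 at 9.18 ± 0.08 and Cd93 at 6.74 ± 0.09, while Cd34 (1.34 ± 0.15) and Cd48 (1.84 ± 0.40) were not. Of 6 MHC class II genes, H2-Ea alone was above it, at 3.82 on replicate 1 and 5.91 on replicate 2 (adjusted p = 0.342, Fisher's exact test). Of 19 imprinted genes, 9 were (adjusted p = 0.754, Fisher's exact test), including Gnas (12.66 ± 0.24) and Grb10 (8.18 ± 0.20).

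Ptprc, the leukocyte common antigen CD45, was not above the floor (1.86 ± 0.09, 0 of its 2 probe sets). Whether these cells had lost the wider blood cell programme was not settled. Haematopoietic transcription factors, a list fixed before the data were seen, were not lost as a group, with 18 of 21 above the floor. That count was known when the question was put, and it does not cover surface genes. Of 11 stem and progenitor surface antigens, Ptprc among them, 5 were above the floor, so a wider loss of such genes stays open. A fault of the Ptprc probe sets was not tested.

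The Gata1 signal of 9.41 stands beside a series text that calls the cells Gata1 null. Whether RNA from globin-rich erythroid cells in the samples was its source was not settled. Most adult globin probe sets were not above the floor, which goes against a large share of such cells. Alpha-globin Hba-a2 was above it by the rule used for genes. The globin values were also known when their median was chosen as the test, so a smaller share stays open. Erythroid cells with little globin RNA are not covered by this test and stay open. The 8 probe sets for adult globin genes had a median of 2.03, below the floor on both arrays, and the 3 of them above the floor stood at 2.94, 3.15 and 4.51. Another transcript binding the probe set cannot be told apart from Gata1 RNA, because only 1 Gata1 probe set could be read. A transcript of an altered allele, or a sample other than its label says, was not tested.

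Of the probe sets above the mean floor, 503 differed by at least 1 between the arrays. A change in the RNA of the gene is argued against, as a set, for the 336 of them whose gene had other probe sets above the floor. The gene's other probe sets moved the same way by a median of 0.0435 (95% interval 0.0147 to 0.0632) beyond the common shift, against 1.18 for the differing probe sets. They moved in the same direction for 197 of the 336. The interval takes probe sets as units, though some share a gene, and measures no spread between arrays. Differing probe sets without such others were not covered. Noise of dim probe sets may account for many, with 4.22% differing below a mean of 6 and 0.903% at or above it, a ratio of 4.67, although the share was 3.43% below 4 and 5.34% from 4 to 6 and so did not rise steadily as probe sets got dimmer. The 103 at or above 6, and single genes with further probe sets that moved the same way, such as Ncf1 and Samhd1, stay open.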
